A study of Mus musculus with 14 samples.

How the data were processed

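RNA from blood leukocytes was measured on 14 one-colour Cy3 Agilent mouse arrays, 1 array per mouse. Per the labels, blood was drawn from the sub-mandibular vein into EDTA, red cells were lysed and the remaining cells were called PBMC; no density gradient or sort is named, so granulocytes, platelets and reticulocytes can be present. The 8 SS mice had lived with a hostile social environment in early life and the 6 SI mice had been isolated as juveniles. All of them received an under-threshold cocaine dose of 5 mg/kg in place conditioning and went through extinction and withdrawal, and blood was taken 24 hours later. Groups were taken from the labels: 4 SS labelled male, 4 SI labelled male, 4 SS labelled female and 2 SI labelled female mice. No mouse without stress or without cocaine was included, so every comparison is between SS and SI.

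The deposited scanner file of each array holds processed signals, median spot signals and median background signals as fluorescence intensity, per the file headers. Background had been subtracted and spatial trends removed by Agilent Feature Extraction 10.7.3.1 per the file headers, while the notes of the authors name version 9.1; no scaling between arrays had been applied to these signals. The other deposited columns are flags, per the file headers, for control type, spots well above background, saturation and outlier spots. The authors also deposited a value table on the log2 scale with 27990 probes, of which 27879 are non-control probes of the scanner files. Its normalization is not given in the sources used here. The highest value is 17.7407 in every column of that table. Between 263 and 1683 cells per column are blank, and none of the blank cells is well above background on its array.

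Each array carries 62976 spots, of which 3671 control spots were left out. Spots of the same probe were averaged as log2 processed signal, which gave 55681 probes. The software marked no saturated spot and between 113 and 174 outlier spots per array. Outlier spots were left out before averaging unless a probe had no other spot. Between 34.8% and 47.7% of the non-control spots were well above background. The 75th percentile of all probes departed from the brightness of the arrays by between -0.47 and 0.60 on the log2 scale. Brightness is the median log2 ratio to the mean array, and both measures were centred over the arrays. Each array was instead scaled by the 75th percentile of the 14522 probes that were well above background on all 14 arrays. This departs from the percentile over all non-control probes chosen before the data were examined; it was decided from the scale factors before any test was run, and the counts under the original choice are given with the results. Probes well above background on at least 6 of 14 arrays were tested, 24033 in all. Gene symbols came from the RefSeq table supplied with the data: 26425 of 31063 probes with a RefSeq-type identifier were matched, and 11497 genes among the tested probes had a symbol. A gene is represented by its tested probe with the highest mean signal. The arrays were designed on an earlier genome build than that table, so no positions are given.

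Models were fitted with limma 3.58.1 in R 4.3.3, and files were read with data.table (version 1.17.8). SS was compared with SI in all mice with the sex label as a term, and within labelled males, within labelled females and as the difference between the sex labels in a fit with 4 groups. The array files place all labelled males on 1 slide and all labelled females on the other, so sex label and slide are the same term. SI mice lie in columns 1 and 2 on the slide of the labelled males and in column 1 on the other, and SS mice in columns 3 and 4 on both, so stress group and column cannot be separated by the design. P values are two-sided and were adjusted by Benjamini-Hochberg over all tested probes at 0.05. The 27 gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 27 lists in each comparison; camera with an estimated correlation and fry were run beside it. Counts of members are given over all probes tested and adjusted over the list alone. A score per array is the mean centred log2 level of a list; 30 such scores and quality measures were compared between SS and SI by exact permutation within slides, two-sided, and adjusted by Benjamini-Hochberg over the 30. The code was tested on simulated data with known changes of single probes and of 1 list, with noise independent between probes. A log2 change of 1 was recovered for 44.8% of probes in all mice, 11.9% in labelled males and 4.48% in labelled females. A change of 2 was recovered for 83.3%, 60.6% and 45.5%. False calls were 10 of 99, 4 of 53 and 3 of 36. Most changes of 1 are therefore missed within a sex label. The raised list was the only list called.

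The lists, the tests, most alternatives and the rule for naming genes were fixed before the data were examined. The rule took the 10 largest rises and 10 largest falls among genes that passed in all mice, and 5 in each direction in the other comparisons (filled by the lowest p where fewer passed). It also took up to 4 members of each list with the lowest p, the Y-linked genes and Xist, and the hemoglobin genes; names that are only clone or locus identifiers were passed over. Of the genes so taken, 2 are not reported here. The platelet, coagulation and angiogenesis lists were included with knowledge that the group behind these data works on clotting and vasculature, so they are not independent of the study.

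Alternatives changed 1 choice at a time, except that normexp changed signal, background and scaling together and the deposited table changed processing and probes. They were quantile scaling, scaling by the median, normexp background correction with an offset of 50 followed by quantile scaling (on median spot signals, as mean spot signals are not in the files used here), the deposited log2 table, no filter on dim probes, and a filter of all 14 arrays. Others were a variance trend with robust fitting, array weights, array row as a block, erythroid or neutrophil level as a covariate, hemoglobin probes left out before scaling, no sex term, equal weight of both sexes, each sex alone, 1 probe per gene, and each array left out in turn. The percentile over all probes, platelet level as a covariate and array brightness as a covariate were added after the data had been seen. Scan day differs only between the slides and was not used. Other splits of the mice within slides were refitted, all of them where there were at most 100 and otherwise 100 drawn with seed 1. The small numbers of mice and the spread between them limit the precision of all comparisons. An array has no counting error that could be computed from the files.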

Results

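Transcripts of blood leukocytes were compared between 8 mice that had met a hostile social environment in early life (SS) and 6 mice isolated as juveniles (SI), all sampled 24 hours after withdrawal from a low cocaine dose of 5 mg/kg. The SS group held 4 labelled male and 4 labelled female mice, and the SI group 4 labelled male and 2 labelled female mice. Hemoglobin transcripts took between 2.0% and 5.6% of the summed signal of an array, and no hemoglobin gene passed between SS and SI. The log2 difference was -0.09 for Hba-a1, 0.00 for Hba-a2, -0.26 for Hbb-b2, -0.19 for Hbb-bt and 1.00 for the embryonic globin Hbb-y (limma adjusted p = 0.374 for the last and higher for the others). The hemoglobin share differed by -0.68 percentage points (SS minus SI, exact p = 0.279 within slides), with 0.13 in labelled males and -1.90 in labelled females (exact p = 0.067, the smallest possible). The groups also differed in the share of spots well above background by 1.00 percentage points (exact p = 0.474) and in overall array brightness by -0.07 on the log2 scale (exact p = 0.872). The main axis of variation, 64.0% of the variance, separated the slides and with them the sex labels. Correlations between arrays of a group, across probes, ran from 0.927 to 0.989 except among SI labelled males, where mice 4 and 7 correlated at 0.833; mouse 4 was also the dimmest labelled male array, at -1.06 against the mean array on the log2 scale.

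Y-linked transcripts went against the sex labels on all arrays. Eif2s3y, a translation initiation factor encoded on the Y chromosome, averaged -1.44 ± 0.18 (SD, scaled log2 signal, n = 6) in labelled females and -7.98 ± 0.50 (n = 8) in labelled males. It was well above background on 6 of 6 labelled female and 0 of 8 labelled male arrays. Ddx3y, a Y-linked RNA helicase, showed the same division, with means of -2.87 ± 0.14 and -7.87 ± 0.51. Xist, the RNA that coats the inactive X chromosome of females, was well above background on 5 of 8 labelled male and 0 of 6 labelled female arrays with its brighter probe. Probes of Kdm5d, Uty, Usp9y and Zfy1 were not above background on any array. The words labelled male and labelled female below name the groups as deposited, and any direction drawn between them rests on those labels. The SS and SI labels were also used as deposited, and no gene was available to check them.

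**Figure D1:**
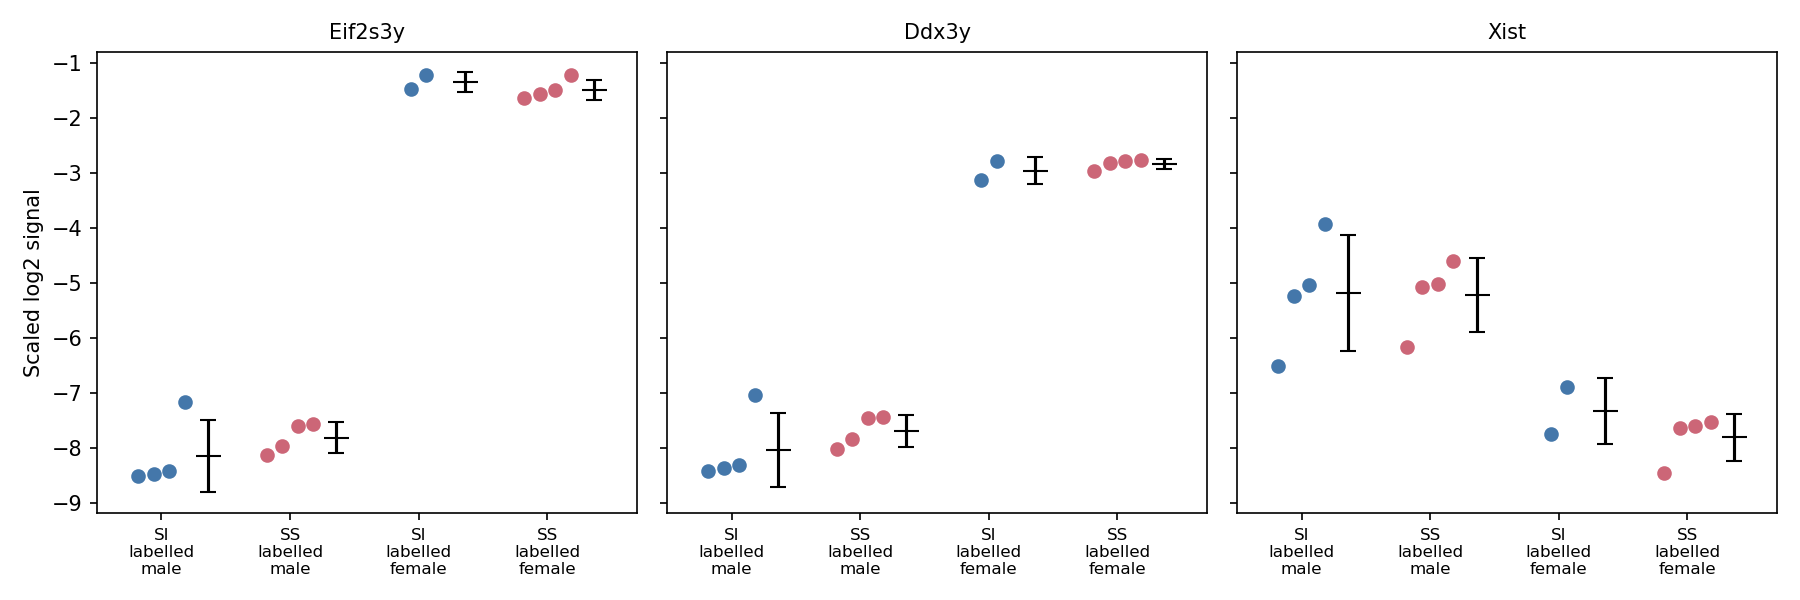
Scaled log2 signal (vertical axis) of the Y-linked genes Eif2s3y and Ddx3y and of the brighter Xist probe in the 4 groups; points are arrays, sorted within a group, and bars give the mean ± SD. Eif2s3y averages -1.44 in the 6 labelled female and -7.98 in the 8 labelled male arrays, while Xist averages -7.65 and -5.20.

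The comparison of SS with SI in all mice asks which blood transcripts distinguish the 2 early social experiences during cocaine abstinence. Genes of platelets and their precursor, the megakaryocyte, rose in SS mice: 33 of 35 measured members of the platelet list rose and none fell, with a median log2 change of 1.48, a 2.79-fold increase (8 SS and 6 SI mice). Among them were Fermt3, which activates integrins on platelets (1.46 ± 0.24, SE), Clec1b, the platelet receptor for podoplanin (1.57 ± 0.26), P2ry12, the ADP receptor that drives aggregation (1.68 ± 0.29), and F5, coagulation factor V (1.36 ± 0.24), each at limma adjusted p = 0.00474. Adjusted over the list alone, 34 members rose. On each slide the mean platelet level of every SS array lay above that of every SI array. In labelled males it averaged 0.78 ± 0.35 (SD, n = 4) against -0.49 ± 0.79 (n = 4), a difference of 1.26 (exact p = 0.029). In labelled females it averaged 0.36 ± 0.17 (n = 4) against -1.31 ± 0.25 (n = 2), a difference of 1.67 (exact p = 0.067, the smallest that 4 against 2 mice allow). Over both slides the difference was 1.43 (exact p = 0.001, adjusted p = 0.029 over 30 measures). The list passed camera at adjusted p = 2.5e-30; adjusted p = 0.351 with an estimated correlation, and 0.00432 with fry. With platelet level as a covariate, which itself follows the stress group, no member passed.

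**Figure D2:**
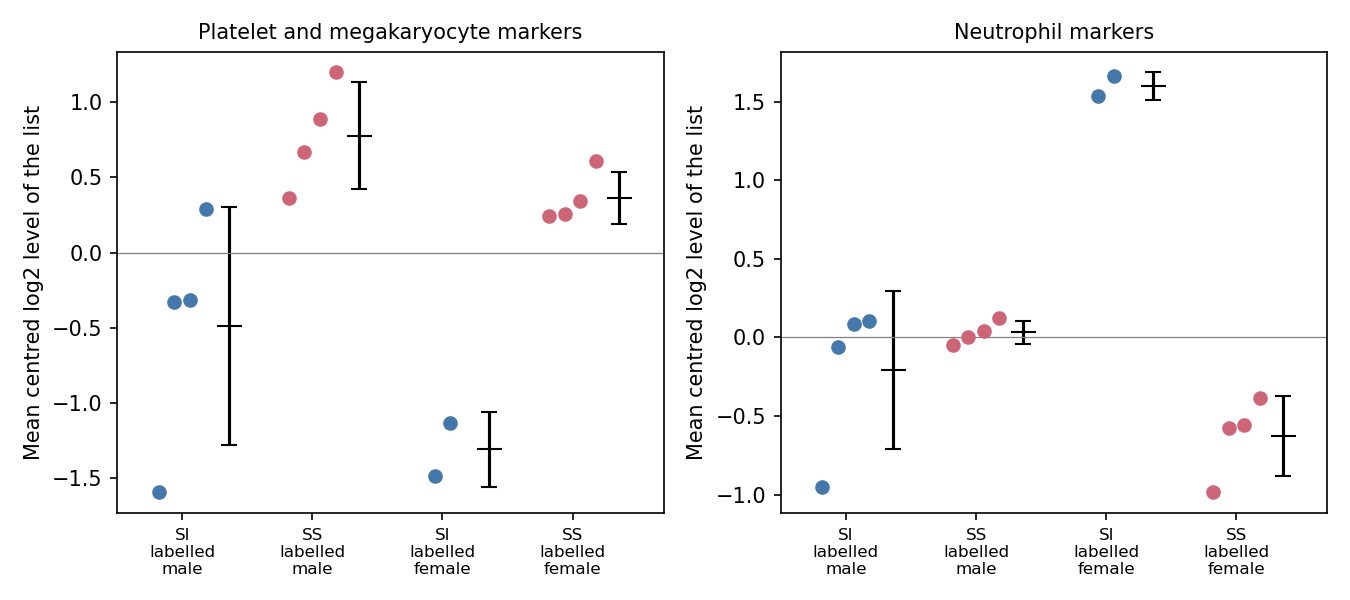
Mean centred log2 level (vertical axis) of the platelet list and of the neutrophil list in the 4 groups; points are arrays, sorted within a group, and bars give the mean ± SD. Platelet levels average -0.49 and 0.78 in SI and SS labelled males and -1.31 and 0.36 in SI and SS labelled females; neutrophil levels differ by -2.22 in labelled females and by 0.24 in labelled males.

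Some genes of coagulation and of blood vessel growth, many of them also made or stored by platelets, rose in SS mice too. In the coagulation list 11 of 27 measured members rose and none fell, with a median log2 change of 0.54; adjusted over the list alone, 13 rose and 2 fell. Examples are Pros1, the anticoagulant protein S (1.34 ± 0.24, SE), Serpinb2, an inhibitor of plasminogen activators (2.04 ± 0.37), and F2r, a thrombin receptor (0.96 ± 0.17). In the angiogenesis list 6 of 15 members rose and none fell, also adjusted over the list alone (median 0.31, mean 0.54). These were led by Angpt1, a ligand of the endothelial receptor Tek (1.63 ± 0.28), Pdgfa, a growth factor (1.41 ± 0.27), Esam, an adhesion molecule of endothelium and platelets (1.33 ± 0.25), and Thbs1, thrombospondin of platelet granules (1.42 ± 0.27). Camera gave adjusted p = 2.2e-04 for coagulation and 0.00642 for angiogenesis; adjusted p = 0.351 with an estimated correlation for both. By exact permutation of the scores within slides the angiogenesis difference was 0.54 (adjusted p = 0.029; 0.49 in labelled males and 0.61 in labelled females) and the coagulation difference 0.54 (adjusted p = 0.160; 0.57 and 0.50). The platelet, coagulation and angiogenesis lists are not independent of the study, and they share members such as F5, F13a1 and Thbs1.

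Several other lists had few members that moved, and most of these members are also known from the megakaryocyte lineage. Lat, a signalling adaptor of T cells and platelets, was the 1 T cell marker that rose (1.24 ± 0.19, SE), and Itga2, a collagen receptor chain of NK cells and platelets, was the 1 NK marker that rose (1.5 ± 0.25). Gata2, a transcription factor of mast cells and blood progenitors, rose in the eosinophil, basophil and mast cell list (1.69 ± 0.28). Gata1 and Tal1, transcription factors of red cell and megakaryocyte precursors, and Sptb, a spectrin of the red cell skeleton, rose in the erythroid list (1.48 ± 0.26, 1.12 ± 0.25 and 1.41 ± 0.34). F13a1, a coagulation factor subunit of platelets and monocytes, rose in the monocyte list (1.30 ± 0.26), in which Nr4a1, a nuclear receptor induced by cell stimulation, fell (-0.88 ± 0.22). None of these lists passed camera: the median log2 change was -0.61 for T cells (adjusted p = 0.269), -0.61 for NK cells (0.231), -0.44 for eosinophils, basophils and mast cells (0.523), -0.37 for erythroid genes (0.895) and -0.39 for monocytes (0.115). B cell and dendritic cell markers had no member that passed, with medians of 0.00 (mean -0.01, camera direction up, adjusted p = 0.852) and -0.20 (0.852).

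Camera called 5 lists lower in SS mice, although few or none of their members passed. In the NF-kB and cytokine list 2 of 29 members fell, Csf1, the growth factor of monocytes and macrophages (-1.16 ± 0.23, SE), and Traf1, an adaptor of TNF receptors (-0.67 ± 0.19). The median log2 change was -0.52 (1 fell adjusted over the list alone; camera adjusted p = 4.4e-04). In the glucocorticoid list 1 of 27 members fell, Tgm2, a transglutaminase (-1.0 ± 0.24), with a median of -0.46 (camera adjusted p = 0.0205). Neutrophil markers had a median of -0.80 with no member passing of 26 (camera adjusted p = 0.00121), which came from labelled females (-2.10) and not from labelled males (0.21), and cytosolic ribosomal proteins one of -0.23 with no member passing of 61 (4.4e-04). The type I interferon list had a median of -0.33 (camera adjusted p = 0.0365), yet its 1 member of 31 that passed, the interferon-induced Ifit2, rose (1.24 ± 0.23). For all of these 5 lists adjusted p = 0.905 with an estimated correlation, and fry gave between 0.124 and 0.292. The neutrophil call was lost without SI labelled female 27 (median -0.55, camera adjusted p = 0.078), and the interferon call without any 1 of SI labelled male 4, SS labelled male 3, SI labelled female 27 or SS labelled female 23 (up to 0.410). The glucocorticoid and interferon calls were also lost in the deposited log2 table (both 0.0915), and the scaling alternatives turned none of the 8 directions.

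The 10 genes with the largest rises were Mill2, an MHC class I-like surface protein (2.20 ± 0.34, SE), Rgs6, a regulator of G protein signalling (2.16 ± 0.38), Peg10, an imprinted gene derived from a retrotransposon (2.12 ± 0.29), Dennd2c, of a family of Rab exchange factors (2.06 ± 0.34), and Serpinb2 (2.04 ± 0.37). They also included Ptprn, a protein of secretory granules (1.98 ± 0.35), Layn, a hyaluronan receptor (1.97 ± 0.30), Lekr1 (1.94 ± 0.31), Sardh, a mitochondrial enzyme of sarcosine breakdown (1.91 ± 0.34), and Acer2, a ceramidase (1.90 ± 0.40). Peg10 was below background on the SI arrays and so at least 2.57-fold higher. Rgs6 was well above background on 1 of 4 SI labelled male and 0 of 2 SI labelled female arrays, and Lekr1 on 2 and 0. Mill2, Dennd2c and Ptprn were so on 0 of 2 SI labelled female arrays. The sizes of these changes rest in part on signals near background. The limma adjusted p was 0.00474 for the 10 genes except Acer2 (0.00793). They kept the call without any 1 array and lost it with platelet level as a covariate; Rgs6 and Lekr1 also lost it in the deposited log2 table (0.0988 and 0.0817).

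The 10 largest falls included leukocyte genes: Cxcr1, a chemokine receptor of neutrophils (-1.74 ± 0.47, SE, limma adjusted p = 0.0333), Ccrl2, a receptor that binds chemerin (-1.16 ± 0.22, 0.00516), and Csf1 (-1.16 ± 0.23, 0.00566). Also lower were Xdh, the enzyme that makes uric acid (-1.52 ± 0.38, 0.0206), Vsig10, an immunoglobulin domain protein (-1.46 ± 0.34, 0.0152), Fbxo10, a ubiquitin ligase subunit (-1.32 ± 0.24, 0.00498), and Myo1d, an unconventional myosin (-1.23 ± 0.26, 0.00827). The remaining ones were the kinase Dstyk (-1.59 ± 0.46, 0.0470), the membrane cytochrome Cyb561 (-1.25 ± 0.35, 0.0412) and the Arf regulator Agap1 (-1.12 ± 0.29, 0.0240). Dstyk was well above background on 0 of 4 SS labelled male and 1 of 4 SS labelled female arrays, Vsig10 on 1 and 0 and Fbxo10 on 0 and 2. The sizes of their falls rest in part on signals near background. Single arrays ended some of the calls. Cxcr1 no longer passed without SI labelled male 5 or 6, SS labelled male 1 or 3, SI labelled female 27 or 28 or SS labelled female 20 (highest adjusted p = 0.12), and Xdh without SI labelled male 6, SS labelled male 2 or SI labelled female 27 (0.0544). Agap1 was lost without SI labelled male 5 or 6, SS labelled male 1 or SI labelled female 27 or 28 (0.0822). Cyb561 held only without SI labelled male 4, SS labelled male 2 or 01b or SS labelled female 21 (0.102 at the highest), and Dstyk only without SI labelled male 5 or 6 or SS labelled female 20 or 22 (0.0952). In the deposited log2 table Cxcr1, Dstyk, Xdh, Vsig10, Cyb561 and Agap1 did not pass.

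In total 1918 of 24033 probes passed in all mice with limma, 1781 higher and 137 lower in SS (92.9% higher), or 990 genes higher and 110 lower of 11497; the median log2 change of all tested probes was -0.04. With the percentile over all probes as scale, 1296 were higher and 74 lower. The count was 3864 (2411 higher and 1453 lower) without SI labelled male 4, and 0 with platelet level as a covariate, where the median absolute log2 change of the 1918 probes went from 1.07 to 0.213 (median SE 0.222 and 0.268).

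**Figure D3:**
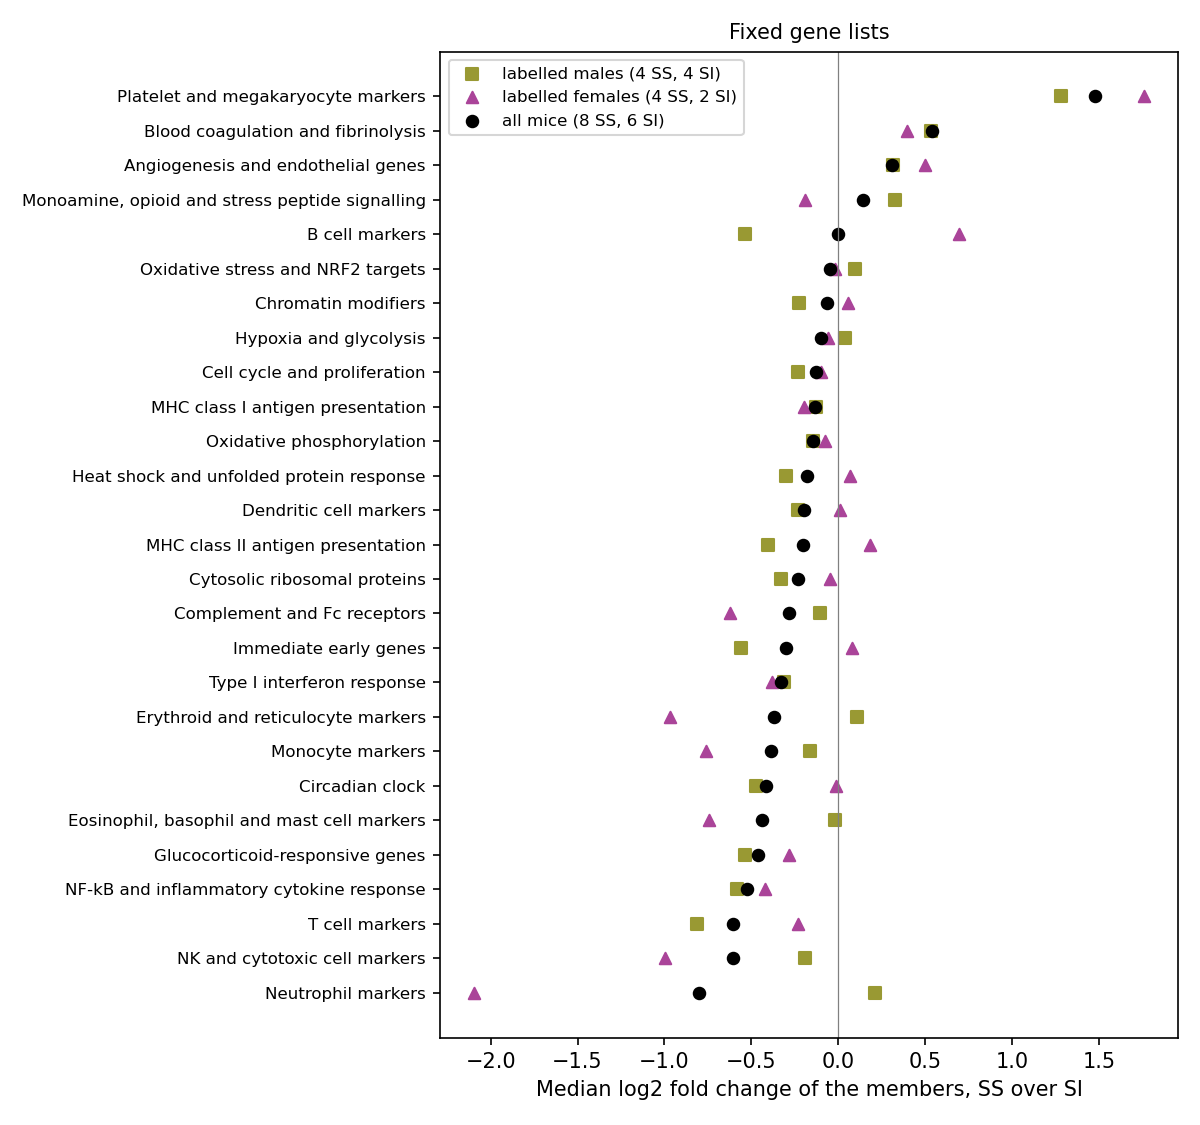
Median log2 change of SS over SI (horizontal axis) of the measured members of the 27 fixed gene lists, in all mice (circles; 8 SS, 6 SI), labelled males (squares; 4 SS, 4 SI) and labelled females (triangles; 4 SS, 2 SI). The platelet list lies at 1.48, 1.28 and 1.76, and the neutrophil list at -0.80, 0.21 and -2.10.

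The comparison within labelled males asks the same question on a single slide, with 4 SS and 4 SI mice. No gene passed, and the platelet genes had the clearest difference: 34 of 35 were higher when adjusted over the list alone, with a median log2 change of 1.28. Fermt3 differed by 1.37 ± 0.32 (SE) and Nrgn, a calmodulin-binding protein found in platelets, by 1.47 ± 0.37. Adjusted over the list alone, 12 of 27 coagulation genes (median 0.53), 6 of 15 angiogenesis genes (0.32) and 4 of 18 monoamine genes (0.33) were also higher. Without single arrays the angiogenesis median ranged from 0.22 to 0.68 and the monoamine median from 0.13 to 0.88. Among the single genes with the lowest p, Cds1, an enzyme of phospholipid synthesis, Peg10 and Cdkn2b, a cell cycle inhibitor, were below background in SI and so at least 3.59-fold, 2.57-fold and 2.32-fold higher. Gcsam, a signalling protein of germinal centre B cells (1.34), and F2r (1.16) were also on the higher side. On the lower side were Ccrl2 (-1.32), Ncapd3, a condensin subunit (-1.29), Ogt, the enzyme that adds GlcNAc to proteins (-1.11), Poc5, a centriole protein (-1.03), and the palmitoyltransferase Zdhhc12 (-0.92).

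With limma 0 of 24033 probes passed in labelled males (lowest adjusted p = 0.0738), although 5706 had an unadjusted p under 0.05; the deposited log2 table gave 212, normexp 1425, quantile scaling 2 and median scaling 2. Without SI labelled male 4, 9424 probes passed (5292 higher, 4132 lower), and 1 passed without SS labelled male 3, SI labelled female 27 or SI labelled female 28. Lists that passed camera were platelet (adjusted p = 1.6e-20), coagulation (6.6e-04), angiogenesis (0.0279), monoamine (0.0261) and oxidative stress (0.0369) on the higher side. Ribosomal proteins (median -0.33, 5.1e-06), NF-kB (-0.58, 8.1e-04), immediate early genes (-0.56, 0.0320), B cells (-0.54, 0.0369) and glucocorticoid genes (-0.53, 0.0444) passed on the lower. None held otherwise: adjusted p = 0.657 with an estimated correlation for the platelet, coagulation and angiogenesis lists, 0.827 for monoamine genes and 0.865 for the others. Single arrays ended the B cell call (5 of 14, up to 0.0914), the glucocorticoid call (4, up to 0.0814), the immediate early and oxidative stress calls (3 each, up to 0.0571 and 0.0628) and the monoamine call (2, up to 0.0571).

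The comparison within labelled females, 4 SS against 2 SI mice, showed lower neutrophil genes in SS beside the higher platelet genes. In the neutrophil list 15 of 26 members fell, 21 adjusted over the list alone, and none rose, with a median log2 change of -2.10. The largest falls were those of granule proteins: Ltf, lactoferrin (-4.87 ± 0.73, SE, limma adjusted p = 0.0111), Ngp, neutrophilic granule protein (-4.85 ± 0.63, 0.00940), Camp, the cathelicidin peptide (-4.63 ± 0.63, 0.00940), Lcn2, an iron-sequestering lipocalin (-4.10 ± 0.45, 0.00367), and Wfdc21, a secreted WAP domain protein (-4.01 ± 0.53, 0.00940). The size of these falls depends on which SI mouse is used: without SI labelled female 28 and 27 respectively, Ltf had -3.29 and -6.44, Ngp -3.31 and -6.39 and Camp -3.36 and -5.90. The SE assume the same spread in all groups, while the 2 SI labelled females had larger SDs (2.23 for Ltf, 2.18 for Ngp and 1.79 for Camp). Hemoglobin share and erythroid genes (median -0.97; camera adjusted p = 0.137) were also lower in SS labelled females, so red cell RNA moved together with the neutrophil genes there. All 4 SS arrays had a lower mean neutrophil level than both SI arrays, at -0.62 ± 0.25 (SD, n = 4) against 1.60 ± 0.09 (n = 2), a difference of -2.22 (exact p = 0.067, the smallest possible). In labelled males the same level differed by 0.24 (exact p = 0.571), and over both slides by -0.75 (exact p = 0.050, adjusted p = 0.216). Camera gave the list adjusted p = 9.2e-23 in labelled females; adjusted p = 0.0516 with an estimated correlation, and 2.1e-04 with fry.

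**Figure D4:**
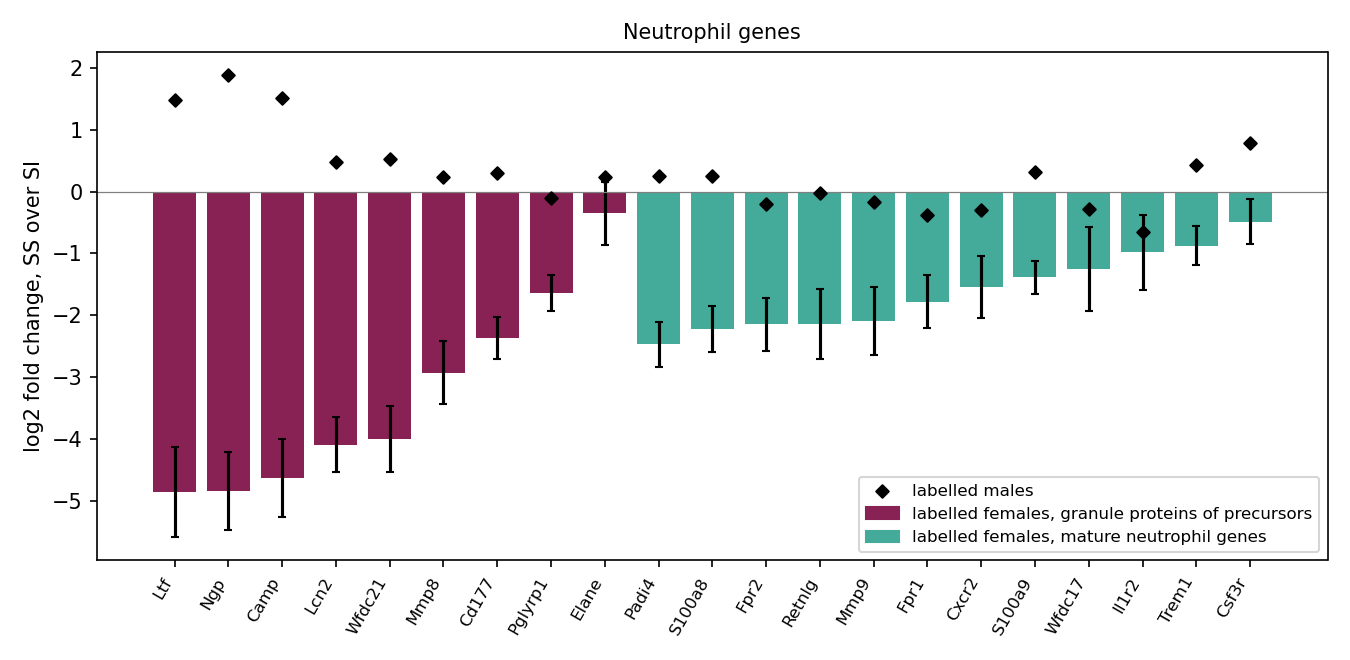
log2 change of SS over SI (vertical axis) of 21 neutrophil genes in labelled females (bars, with SE; 4 SS, 2 SI) and labelled males (diamonds; 4 SS, 4 SI); bar colours part granule proteins made by precursors from genes of mature neutrophils, 2 sets drawn up after the largest falls were seen. In labelled females the medians are -4.01 over the 9 granule protein genes and -1.66 over the 12 mature genes.

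Platelet genes rose in labelled females for 23 of 35 members (33 adjusted over the list alone; median 1.76), including Rgs18, a regulator of G protein signalling in platelets (2.14 ± 0.40, SE), Cd9, a tetraspanin (1.76 ± 0.34), Clec1b (1.99 ± 0.40) and P2ry12 (2.15 ± 0.44). Mill2 (3.08 ± 0.45, limma adjusted p = 0.0111), Rgs6 (2.73 ± 0.58, 0.0284) and Dennd2c (2.71 ± 0.51, 0.0214) were below background in SI, hence at least 6.34-fold, 5.25-fold and 4.92-fold higher, and Triqk rose by 2.64 ± 0.43 (0.0156). Of the coagulation list 4 of 27 rose (12 rose and 2 fell adjusted over the list alone; median 0.40), and of the angiogenesis list 3 of 15 (6; median 0.50), among them Pdgfa (2.05 ± 0.37). The angiogenesis median was 0.33 without SI labelled female 27 and 1.32 without SI labelled female 28. The chaperone Hspa1a rose (2.39 ± 0.53) while Asns, asparagine synthetase, fell (-1.43 ± 0.21), as did C3, the central complement protein (-1.58 ± 0.34), and Cybb, the NADPH oxidase chain of phagocytes (-1.13 ± 0.29).

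Camera also passed B cell markers on the higher side (median 0.69, no member of 18 passing, adjusted p = 0.00182). On the lower side it passed monocyte (-0.76; 1 of 21 rose and 1 fell, 1 and 8 adjusted over the list alone; 3.6e-04), NK (-1.0; 1 of 17 rose; 0.0146) and NF-kB markers (-0.42; none of 29; 0.0246). With an estimated correlation, adjusted p = 0.589 for the platelet and angiogenesis lists, 0.613 for coagulation and monocytes, 0.876 for B cells and NK cells and 0.940 for NF-kB. Without SI labelled female 27 the calls of B cells (median 0.15), monocytes (-0.23), NF-kB (-0.23) and NK cells (-0.94) were lost; that of NF-kB was also lost without SS labelled female 23. These lists passed in labelled females; the tests of the difference between the sex labels follow.

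In labelled females 962 probes passed with limma, 766 higher and 196 lower (452 and 117 genes; median of all tested probes -0.11), and 909 higher and 121 lower with the percentile over all probes. The count rests on few mice, as only 2 SI labelled females exist and a lone remaining one is assumed to vary like the other groups. It was 43 without SS labelled female 23 (16 higher, 27 lower), 54 without SI 28 (22 and 32) and 183 without SI 27 (68 and 115), so the balance of directions turned. It was 84 without SS 20 (46 and 38), 98 without SS 21 (55 and 43) and 194 without SS 22 (117 and 77); leaving out labelled males 2, 01b, 5 or 4, which share the estimate of spread, gave 482, 517, 565 and 1919. Without SI labelled female 28 Ltf, Camp, Wfdc21, Mill2, Rgs6, Dennd2c and Triqk no longer passed (adjusted p from 0.0538 for Camp to 0.158 for Rgs6), while Lcn2 and Ngp passed without any 1 array. Rgs6 was also lost without any 1 other labelled female array, Dennd2c without SS labelled female 20, 21 or 23 (up to 0.0704) and Triqk without SI labelled female 27 or SS labelled female 23 (up to 0.0583).

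The difference between the sex labels in the response to SS against SI was carried by neutrophil granule genes, which differed most. Ngp (-6.74 ± 0.82, SE, limma adjusted p = 0.0150), Ltf (-6.35 ± 0.94, 0.0353), Camp (-6.14 ± 0.81, 0.0171), Lcn2 (-4.58 ± 0.58, 0.0150) and Wfdc21 (-4.53 ± 0.69, 0.0405) responded more negatively in labelled females than in labelled males. In labelled males their own log2 changes lay between 0.49 and 1.89 and did not pass. Scaled log2 levels of Ngp averaged 2.63 in SI and -2.22 in SS labelled females, and -3.00 and -1.10 in SI and SS labelled males. Those of Camp averaged 5.58 and 0.95, and 0.15 and 1.66, in the same order. All 5 genes had their highest group mean in the 2 SI labelled females, although levels on different slides are not strictly comparable. The SE and p values assume the same spread in all 4 groups. For Ngp, Ltf and Camp the 2 SI labelled females had SDs of 2.18, 2.23 and 1.79, against 0.22 to 0.80 in the other groups. The precision for these genes is therefore overstated. Crispld2, a secreted protein that the naming rule did not take and that was added after its value was seen, also passed (-3.04 ± 0.48, 0.0499). Xpo7, a nuclear export receptor (2.20 ± 0.45, 0.112), Hdac9, a histone deacetylase (2.24 ± 0.46, 0.115), Tchp, a keratin-binding protein (1.78 ± 0.42, 0.183), and Ogt (1.45 ± 0.35, 0.192) did not pass. In the neutrophil list 5 of 26 members responded more negatively in labelled females (20 adjusted over the list alone; median -1.90; camera adjusted p = 5.8e-27), and the list also passed with an estimated correlation (adjusted p = 0.0274).

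Lists with camera calls for this difference were B cells (median 1.25, adjusted p = 2.2e-06), ribosomal proteins (0.30, 0.00188), heat shock genes (0.35, 0.0176) and platelet genes (0.41, 0.0176) on the higher side in labelled females. On the lower side were monocytes (-0.66, 2.9e-04), NK cells (-0.67, 0.0176) and erythroid genes (-1.06, 0.0188), and no member of these 7 lists passed. With an estimated correlation, adjusted p = 0.892 for B cells and monocytes and 0.919 for the others. Without single arrays the erythroid call was lost 7 times of 14 (up to 0.258), the NK call 5 times (0.160), the platelet call 4 times (0.867) and the ribosomal, heat shock and monocyte calls once each (0.0644, 0.149 and 0.539), the last 2 without SI labelled female 27. The count of 11 probes (1 higher, 10 lower; 3030 at an unadjusted p under 0.05) was 664 without SI labelled male 4, 88 without SI labelled female 27 and 22 without SI labelled female 28. It was 6 without SI labelled male 6, SS labelled male 01b, SS labelled female 20 or SS labelled female 21, 4 without SS labelled male 2, SI labelled male 5 or SS labelled male 3. It was 1 without SS labelled female 23, where the granule genes Ngp, Ltf, Camp, Lcn2 and Wfdc21 no longer passed (from 0.0518 upwards). Camp was also lost without the 3 arrays that left 4 probes. Ltf held only without SI labelled male 4 or 7, SS labelled male 1 or SI labelled female 27, and Wfdc21 only without SI labelled male 4 or 7 or SI labelled female 27. Wfdc21 also lost its call with quantile, median and all-probe percentile scaling. A difference of slide response cannot be separated from one of sex label.

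Agreement of the SS against SI change between the slides was positive for rising genes. Of 452 genes that rose in labelled females, 449 had a positive log2 change in labelled males; of 117 that fell, 71 had a negative one. Across 11497 genes, which are not independent replicates, Pearson's r of both log2 changes was 0.271 and Spearman's rho 0.162, with the same sign in 58.8% of genes; without the platelet list r was 0.260. Of 100 relabellings within slides, 19 gave an r as high. Leaving out SI labelled male 4 gave 0.131 and leaving out SI labelled male 7 gave 0.416.

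The comparison of labelled females with labelled males, which is also a comparison of the slides, checks the labels. Eif2s3y and Ddx3y were among the largest rises, at least 40.0-fold and at least 14.8-fold higher in labelled females. C5ar2, a receptor for complement fragments (3.77 ± 0.30, SE), Mc3r, a melanocortin receptor (3.46 ± 0.60), and Il17d, a cytokine (3.44 ± 0.47), were also higher. On the lower side Atp2b2, a calcium pump of the plasma membrane, was at least 161-fold lower in labelled females and Acot3, a peroxisomal thioesterase, at least 154-fold. Pgbd1, a gene derived from a transposase, was at least 144-fold lower, Tead1, a transcription factor of the Hippo pathway, at least 104-fold, and Slc26a1, a sulfate transporter, at least 89.7-fold. In all 9145 probes passed with limma, 2762 higher and 6383 lower (30.2% higher; median of all tested probes -0.07). This balance depends on scaling: 6748 were higher and 4964 lower with the percentile over all probes, where the median of all tested probes moved to 0.34. They were 5059 and 5043 with quantile scaling, 5724 and 5179 with median scaling, 4985 and 4986 with normexp and 1158 and 5843 in the deposited log2 table.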

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

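The tests of the array column, of red cell RNA, of both explanations for the neutrophil genes, of both explanations for the sex labels and of the agreement between slides were chosen only after the result was seen. So were array brightness and platelet level as covariates and the splits without SI labelled male 4.

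Platelet genes were higher in SS mice, with a list median of 1.48 on the log2 scale and rises of 1.42 ± 0.25 and 1.31 ± 0.26 (SE) for the abundant Pf4 and Ppbp, picked after their values were seen. The array column, and handling order with it, cannot be told apart from the stress group: among mice of the same group the platelet level rose by 0.239 per column (95% interval -0.411 to 0.890), and a steady gradient would need 0.632 in labelled males and 0.668 in labelled females. Red cell RNA and array brightness as the whole cause are argued against by medians of 1.53 with erythroid level and 1.46 with brightness as a covariate. A larger share of platelet RNA in the SS preparations is a candidate explanation: among mice of the same group, 957 genes that rose outside the list followed the platelet level with a median correlation of 0.848, against -0.40 for matched genes that did not pass (0.853 and -0.220 without SI labelled male 4; -0.42 against -0.56 for the 110 genes that fell and their matches). These correlations cannot tell platelet RNA from another difference that runs across the arrays. Among labelled males, platelet level departed from the group along the division by brightness. SI mouse 4 had 0.29 against -0.75 for the other SI, and SS mouse 3 had 0.36 against 0.92 for the other SS. Whether the blood held more platelets, the lysis kept more of them or megakaryocyte output changed with early stress was not tested. No sort or gradient that would remove platelets is named in the labels.

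Neutrophil genes were lower in SS among labelled females, with a list median of -2.10 on the log2 scale and values of -2.23, -1.39 and -0.49 for S100a8, S100a9 and Csf3r. A single SI mouse as the cause is argued against by a median of -2.0 at the nearest to 0 when either of the 2 was left out. A lower share of neutrophils of unchanged maturity cannot be told apart from fewer immature ones: the granule genes fell most (median -4.01 for 9 against -1.66 for 12 genes of mature neutrophils), but these sets were drawn up after 5 of the 9 were seen as the largest falls, and other leukocytes also express some of the mature genes. Without those 5, the other 4 granule genes had a median of -2.01, a difference of -0.342 that a share of 0.581 of 10000 random divisions reached. An event shared by both SI mice may remain as an explanation too, and labelled males had medians of 0.49 and -0.094 for the full sets.

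The sex labels differed from the Y-linked genes on 14 of 14 arrays, which is what sex labels exchanged between the slides would give. Whether the labels of the mice or of the slides were exchanged stays open. The slides hold 8 labelled male and 6 labelled female arrays, so a plain exchange of the slides would not keep the group sizes. An exchange of mice could also reach the SS and SI labels, on which every comparison of SS with SI rests. Unspliced or genomic template on the slide of the labelled males may add to the difference. The 4485 probes named by an intergenic interval had a median difference (labelled female minus labelled male) of -0.689 against -0.101 for matched transcript probes, a paired difference of -0.374 (95% bootstrap interval -0.432 to -0.335). Between 24.9% and 32.9% of interval probes were well above background per array on that slide against 17.6% to 21.5% on the other. Sex itself stays untested for all other genes, because sex label and slide are the same term.

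Splits of the mice set these counts beside chance. In all mice 3 of 100 drawn splits, the real one included, gave at least its 1918 probes, out of 1050 splits possible. This share lies under 0.05, but it does not exclude chance. The highest other split called 9209, which points to a structure of the samples. It places the bright SI labelled males 5, 6 and 7 with SS labelled male 3 against the dimmer SI labelled male 4 and SS labelled males 1, 2 and 01b, and the same division, which an exchange of mice 4 and 3 would give, called 14908 probes among labelled males. For the 8 lists 79 of 100 splits gave as many (highest 16), so chance cannot be excluded for that count. In labelled males 35 of 35 splits gave at least the 0 probes of the real one, which a count of 0 fixes in advance, so this share tells nothing. In the same mice 4 other splits reached its 5706 at an unadjusted p under 0.05. Without SI labelled male 4, 2 of 35 gave at least 9424 (highest other 13701), so chance cannot be excluded. The 15 splits of labelled females are too few for a share under 0.05, with 962 probes for the real one and 2 for the highest other. For the sex label 1 of 100 drawn splits, the real one, gave 9145 (highest other 6726), a share under 0.05. For the correlation between slides 19 of 100 gave at least 0.271 (highest other 0.596), so chance cannot be excluded.

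Single arrays far from the other 3 of their group were found in 22 of 150 sets of 4 values, from many measures of the same groups of 4 mice. Chance gives about 1 in 20 for a single set. The measures share arrays and many move together, so the 2 rates cannot be set against each other. SS labelled male 3 stood apart for B cell (0.31), T cell (0.52), immediate early (0.73), ribosomal (0.094), circadian (0.55) and chromatin genes (0.12). SI labelled male 4 stood apart for neutrophil (-0.95), NF-kB (-0.67), glucocorticoid (-0.20) and immediate early genes (-0.55), and SS labelled male 1 for glucocorticoid genes (-0.36). SS labelled female 22 stood apart for T cell (-0.083), immediate early (-0.10) and heat shock genes (0.020), the hemoglobin share (2.01%), spots well above background (40.9%) and brightness (0.60). Scaled log2 levels stood apart for Peg10 in SI labelled male 6 (-8.42) and SS labelled male 3 (-6.04), Dennd2c in SI labelled male 6 (-6.07), Acer2 in SS labelled female 23 (-3.23) and Agap1 in SI labelled male 4 (-5.49).

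Camera at the preset correlation called a difference between the sex labels in the response to SS against SI for 8 lists. The medians were 1.25 for B cells, 0.30 for ribosomal proteins, 0.35 for heat shock genes, 0.41 for platelet genes, -0.66 for monocytes, -0.67 for NK cells, -1.06 for erythroid genes and -1.90 for neutrophils. Only the last also passed with an estimated correlation, where camera gave the others adjusted p from 0.892 to 0.919. Single genes that differed were Ngp (-6.74), Ltf (-6.35), Camp (-6.14), Lcn2 (-4.58) and Wfdc21 (-4.53).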

How the results depend on the processing

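Platelet level and array brightness as covariates and the percentile over all probes were chosen after the data had been seen. Scan day was not run, as it differs only between slides, and a variance trend gives no new correlation between slides because it leaves the log2 changes as they are. Of the other values of single genes, 798 kept their direction and side of the threshold, 86 lost and 52 gained a call, and of the list values 423 kept both and 125 lost a call. Leaving out arrays, 745 gene values kept both, 80 lost and 15 gained a call, and 430 list values kept both and 46 lost a call. Probes near background limit the precision, and a filter of all 14 arrays leaves out genes expressed in a single group. The cause was not tested unless named.

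Probes passing in all mice (1918) were 1125 with no filter on dim probes, where more probes are tested, and 1147 with no sex term. They were 6807 with array weights, 6979 with erythroid, 598 with neutrophil, 4425 with brightness and 0 with platelet level as a covariate; without single arrays they ranged from 1488 to 3864. Platelet level follows the stress group, so that fit removes the difference it is set beside (median absolute log2 change 0.213, SE 0.268).

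In labelled males (0) they were 2 with quantile scaling, median scaling, the percentile over all probes and brightness. They were 1425 with normexp, 212 in the deposited log2 table, 14038 with array weights, 5353 with erythroid and 7043 with neutrophil level, and 0 to 9424 without single arrays. In labelled females (962) they were 434 in the deposited table, 52 with no filter (18 higher, 34 lower), and 543 with array row as a block. They were 2750 with erythroid, 3277 with neutrophil (1047 higher, 2230 lower), 3236 with brightness and 0 with platelet level, 1706 from labelled female arrays alone, and 43 to 1919 without single arrays. For the difference between sex labels (11) they were 17 with quantile scaling and 42 in the deposited table (22 higher, 20 lower). They were 2394 with array weights, 77 with erythroid, 8258 with neutrophil, 19 with platelet and 162 with brightness as covariates, and 1 to 664 without single arrays. For the sex label (9145) they were 3917 with the filter of all 14 arrays, where fewer probes are tested, 14402 with array weights, 14140 with brightness, and 7929 to 9863 without single arrays.

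The 8 lists became 0 with an estimated correlation and 4 with fry, and 8 to 11 without single arrays. The correlation between slides (0.271) was 0.479 with normexp, 0.080 with no filter, 0.456 with the filter of all 14 arrays, 0.150 with array weights, 0.372 with erythroid and 0.426 with brightness. It reversed to -0.185 with neutrophil and to -0.300 with platelet level, and ranged from 0.131 to 0.416 without single arrays.

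Reversals of lists are given as medians; where the sign of the median did not turn, the test did. With platelet level, in all mice, angiogenesis had 0.029, coagulation 0.013, ribosomal 0.29, glucocorticoid 0.23, NF-kB 0.16 and platelet genes -0.0019, and Acer2 -0.0043. In labelled females angiogenesis had -0.072, coagulation -0.20, NF-kB 0.41, NK 0.80 and platelet genes -0.027, and the difference between sex labels was -0.050 for platelet genes. In labelled males angiogenesis had 0.019, B cells 0.21, coagulation 0.084, ribosomal 0.18, glucocorticoid 0.25, immediate early 0.39, monoamine 0.0097, oxidative stress 0.049 and platelet genes -0.019. A list set beside its own level has its outcome fixed. Neutrophil level follows the stress group in labelled females (-0.62 ± 0.25 in SS and 1.60 ± 0.09 in SI, SD), so a fit with it cannot separate the 2 there. With neutrophil level labelled females had -0.018 for angiogenesis, -0.31 for coagulation, 2.13 for NF-kB, 1.73 for NK and -0.33 for platelet genes, and the difference between sex labels was 2.46 for NK and -1.80 for platelet genes. That difference was also 0.029 for platelet genes with array weights and 0.30 for erythroid genes with brightness.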

Other observations

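Tests of the agreement between slides, and the comparison of mice 4 and 3 with both groups, were chosen only after the values were seen; the lists here were fixed before the data were examined.

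Antioxidant and glucose-handling genes held rising members in all mice although their lists did not pass. In the oxidative stress list 9 of 27 members rose and 1 fell (10 and 2 adjusted over the list alone). Examples are Gclc, of glutathione synthesis (0.81 ± 0.14, SE), Prdx6, a peroxiredoxin (1.11 ± 0.19), Srxn1, which restores peroxiredoxins (1.45 ± 0.26), and Gpx4, which reduces lipid peroxides (1.23 ± 0.23). Its median was -0.05 while the mean of 0.21 and the test pointed up (camera adjusted p = 0.0598; 0.0375 with fry). In the hypoxia and glycolysis list 8 of 26 rose and none fell (9 and 3 adjusted over the list alone). Rising members were the glucose transporter Slc2a3 (1.33 ± 0.24), the hypoxia-induced Ndrg1 (1.16 ± 0.24), the hexokinase Hk1 (1.09 ± 0.23) and the aldolase Aldoa (0.72 ± 0.15). Its median was -0.10, its mean 0.13 and its test pointed up (0.241). In the monoamine list 4 of 18 rose and none fell (5 adjusted over the list alone). These were the serotonin transporter Slc6a4 (1.61 ± 0.28), which is also a platelet list member, the vesicular transporter Slc18a2 (1.37 ± 0.25), the decarboxylase Ddc (1.33 ± 0.27) and the dopamine transporter Slc6a3 (1.25 ± 0.32). The median was 0.14 (camera adjusted p = 0.0531).

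The remaining lists had few or no members that passed in all mice. Immediate early genes had a median of -0.30 with Nr4a1 falling (camera adjusted p = 0.137), and heat shock genes one of -0.18 with the chaperone Hspa4l rising (1.00 ± 0.24, SE) and Asns falling (-0.97 ± 0.17; 0.852). In oxidative phosphorylation Cox5a and Ndufa4, subunits of respiratory complexes, rose (0.82 ± 0.18 and 0.68 ± 0.16; median -0.14, 0.478). Kif23, a kinesin of cell division, fell in the cell cycle list (-0.98 ± 0.24; median -0.13, 0.852). B2m, the light chain of MHC class I, rose in that list (0.83 ± 0.21; median -0.14, 0.694), while no MHC class II gene passed (-0.20, 0.350). Among chromatin modifiers the methyl-CpG reader Mbd2 and the deacetylase Hdac5 rose (0.63 ± 0.15 and 0.58 ± 0.16; median -0.06, 0.852). Circadian clock (-0.42, 0.430) and complement and Fc receptor genes (-0.28, 0.308) had no member that passed.

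A swap of SI labelled male 4 with SS labelled male 3 could explain that each resembled the other group, and it stays open. In 24 of the 27 lists mouse 4 lay nearer to the mean of the other SS than of the other SI labelled males, in 20 mouse 3 lay nearer to the other SI, and in 19 both did. Examples are B cell genes (-0.54 in mouse 4, 0.31 in mouse 3; means of the others 0.27 in SI and -0.58 in SS) and circadian genes (-0.67 and 0.55; 0.57 and -0.28). Platelet genes (0.29 and 0.36; -0.75 and 0.92) and NF-kB, glucocorticoid and angiogenesis genes placed mouse 3 with SS, as labelled, and mouse 4 also nearer to SS. The lists are not independent, and array brightness divides these mice in the same way. Ngp, a single gene picked afterwards, went with the labels, at -3.16 in mouse 4 (the SI labelled males had -3.17 to -2.71) and -0.89 in mouse 3 (the SS labelled males had -1.77 to -0.81). Mouse 4 also had the highest erythroid level of the labelled males (2.06), and the comparison of labelled males gave 9424 probes without replicate 4. Mice 1 and 01b, whose labels differ by a suffix, correlated at 0.977 and were kept as separate mice.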
